A study of Homo sapiens with 5 samples.

How the data were processed

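RNA was measured on 5 Illumina human BeadChip arrays, 1 for each of 5 cultures of 2 established cell lines from human pancreatic ductal adenocarcinoma, Miapaca and BXPC3. Per the labels' protocols, cells were seeded in multiwell plates, siRNA was added 24 h later, and RNA was taken after 72 h of exposure. Miapaca cells received siRNA at 60 pM, as the labels give it, with 4 µl of lipofectamine RNAiMAX. BXPC3 cells received 200 nM with 14 µl of Xtreme gene9. The unit of the Miapaca dose was printed as the labels state it and could not be checked. Biotin-labelled cRNA was made by a modified Eberwine procedure per the labels, a method that primes on poly(A) tails.

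The siRNA aimed at the LYNX1 open reading frame (ORF) is given in the labels with the sense strand UUACUGACCUUCAUCCUGG and the antisense strand CCAGGAUGAAGGUCAGUAA. The siRNA aimed at the 3′ untranslated region (3UTR) has the sense strand UUGAAGAGGAGAGCAGACC and the antisense strand GGUCUGCUCUCCUCUUCAA. In each pair the 19 bases of one strand are the full reverse complement of the other. Which strand matches the transcript, and which other transcripts match, was not analysed here, since no transcript sequence was used. No genomic coordinates were printed, because the array annotation names no genome build.

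The authors deposited a table of mean bead intensities that, per the file headers and its name, was not normalized between arrays. The same table holds a detection p-value for each probe and array, deposited by the authors, whose method is not given in the sources used here. Detection p-values fell with intensity on each array, at rank correlations of −0.988 to −0.991. Scanner software and any background subtraction before deposit are not given in the sources used here, and control probes were not named. The series matrix deposited by the authors holds intensities on a linear scale after a normalization whose method is not given. Its column medians were 100.0 for the Miapaca control, 102 for Miapaca ORF, 102 for Miapaca 3UTR, 101 for the BXPC3 control and 101 for BXPC3 ORF. Medians of this size show a linear, uncentred scale, and the values had rank correlations of 0.9998 or more with the bead means of the same arrays.

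The table held 48107 probes, and 1 was left out for a missing value. Background was estimated from intensities and detection p-values, and the arrays were corrected by normexp with an offset of 16, quantile-normalized together and put on the log2 scale with neqc in limma 3.58.1 (R 4.3.3). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 did the remaining work. The platform annotation gave 1 gene symbol for 30113 probes, several for 8, and did not list 17985. Symbols were updated through RefSeq accessions for 29077 probes and through Entrez identifiers for 1015, with the GRCh38.p14 gene table used for names only, and 21 were kept as given. The update changed 27 symbols and left 20043 genes. One of the changed probes is listed as LYNX1 in the platform annotation and carries the accession of SLURP2, another Ly6 family gene, so it was read as SLURP2. The probe with the highest mean over the 5 arrays stood for its gene.

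Each siRNA array was compared with the control array of its line. A gene entered where its detection p was under 0.01 on at least 1 of the 2 arrays. A gene detected on only 1 of them was set against the higher of its own value and the lowest detected signal of the dim array, and its change is given as at least that size. Where the brighter array was the undetected one no bound holds, as for HMOX2 with the 3UTR siRNA and TELO2 in BXPC3, which stayed in the counts past 2-fold. Genes were counted at a 2-fold difference. With 1 array per group there was no test of a single comparison and no p-value. Named genes followed a rule fixed before the data were examined. In each comparison it took the 12 highest and 12 lowest genes, LYNX1, detected nicotinic receptor subunits, and up to 4 members of each gene list past 2-fold. It also took genes past 2-fold the same way in all 3 comparisons and the 5 genes with the smallest p in the fit over all arrays. Some of these genes are not named in the text.

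The 24 gene lists were also fixed before the data were examined, with 651 genes on the array. They were nicotinic receptor and Ly6 family, G1/S and DNA replication, G2/M and mitosis, p53 targets and cell cycle arrest, apoptosis and BCL2 family, ATF4 and unfolded protein response, interferon response, and NF-kB and inflammatory mediators. Others were immediate early and ERK target genes, hypoxia and glycolysis, cholesterol and lipid synthesis, epithelial, mesenchymal and TGF-beta targets, ribosomal proteins, mitochondrial respiratory chain, heat shock and chaperones, oxidative stress and NRF2 targets, and metallothioneins. The last were histones, lysosome and autophagy, RNA interference machinery, fibroblast, endothelial and blood cell markers, pancreatic acinar and endocrine markers, and reference genes. A list's median log2 difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and was taken to stand apart below the 2.5 or above the 97.5 percentile. These percentiles describe the arrays at hand and are not tests across replicates. Of 100 random lists of 30 BXPC3 genes with no shift, 7 stood apart, and of 100 lists shifted by −0.3 on the log2 scale, 99 did.

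Replicate spread was estimated in a limma fit (lmFit and eBayes) over all 5 arrays with a term for the line, 2 residual degrees of freedom and Benjamini-Hochberg adjustment. It took the 3 LYNX1 siRNA arrays as replicates of 1 treatment, so differences between siRNAs and lines counted as error. Nothing in the labels says how the 5 cultures relate in time or batch. Gene lists were tested in this fit with camera at a preset correlation of 0.01 and with an estimated one. In simulated data for this fit, with 12842 genes at the observed spread, 0% of genes changed 2-fold and 0% of genes changed 4-fold were recovered. At 0.5 times that spread 54% and 90% were recovered, with 4 false calls.

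The 2 Miapaca comparisons share their control array, so their agreement was set against 100 simulated pairs of unchanged arrays with the spread seen between the ORF and 3UTR arrays. Alternatives fixed in advance were no background correction, an offset of 50, median scaling, quantile normalization within each line, the series matrix values, a detection p of 0.05, detection on both arrays, no filter, the mean over detected probes and a 1.5-fold threshold. For lists they also were unmatched random lists and members at their bound. For the limma fit they were an intensity trend with robust variances, no line term, Miapaca arrays alone and the fit without the 3UTR array. Cyclic loess normalization, and the mean over detected probes in the limma fit, were added after the data had been seen.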

Results

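The series measured gene expression after siRNA against LYNX1, a membrane-anchored Ly6 protein that binds nicotinic acetylcholine receptors, in 2 human pancreatic cancer cell lines. Each of the 5 groups held 1 array. In Miapaca cells an siRNA against the open reading frame (ORF) and another against the 3′ untranslated region (3UTR) were set beside a non-targeting siRNA. In BXPC3 cells the ORF siRNA alone was set beside it. The mean bead intensity was 463 on the Miapaca control array, 355 with the ORF siRNA and 343 with the 3UTR siRNA. On the BXPC3 arrays it was 366 for the control and 361 for the ORF siRNA. Probes detected at a p under 0.01 numbered 17419, 16704, 16622, 18205 and 17689 in the same order. Because no group had replicates, single differences have no error estimate, and the number of arrays limits the precision.

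LYNX1 itself did not reach a detection p under 0.01 on any of the 5 arrays. Its probe for NM_177477 read 104 on the Miapaca control array, 88.9 with the ORF siRNA and 83.1 with the 3UTR siRNA, and 91.0 and 104 on the BXPC3 control and ORF arrays. Its probe for NM_177476 read 103, 89.7, 90.2, 93.0 and 106 on the same arrays, beside a fitted background between 92.4 and 99.5. The smallest detection p of either probe was 0.0228. The knockdown therefore could not be checked. The SLURP2 probe, listed as LYNX1 in the platform annotation, passed detection on the BXPC3 control array only, at 110.

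Nicotinic receptor subunits were detected for 5 of the 14 genes with a probe. CHRNA5, the α5 subunit, was the brightest. It stood at −0.51 (log2 difference from control) with the ORF siRNA and −0.53 with the 3UTR siRNA in Miapaca, and at 0.32 in BXPC3. A different CHRNA5 probe gave −0.44, 0.21 and −0.45, so the probes disagreed in sign in the last 2. CHRNB1, the β1 subunit, stood at −0.10, 0.70 and 0.29. CHRNA2, CHRNA10 and CHRNE lay near the detection limit. Where both arrays passed it, CHRNA10 stood at 0.28 and 0.05 with the ORF and 3UTR siRNA in Miapaca and CHRNA2 at −0.48 in BXPC3. In the nicotinic receptor and Ly6 family list, 9 members were measured in Miapaca and 14 in BXPC3, and the list medians were −0.06, −0.35 and −0.18, all inside the middle 95% of matched random lists. Of its members, PLAUR, the urokinase receptor, was 3.39-fold higher and LY6E was 2.08-fold lower with the ORF siRNA in Miapaca.

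**Figure D1:**
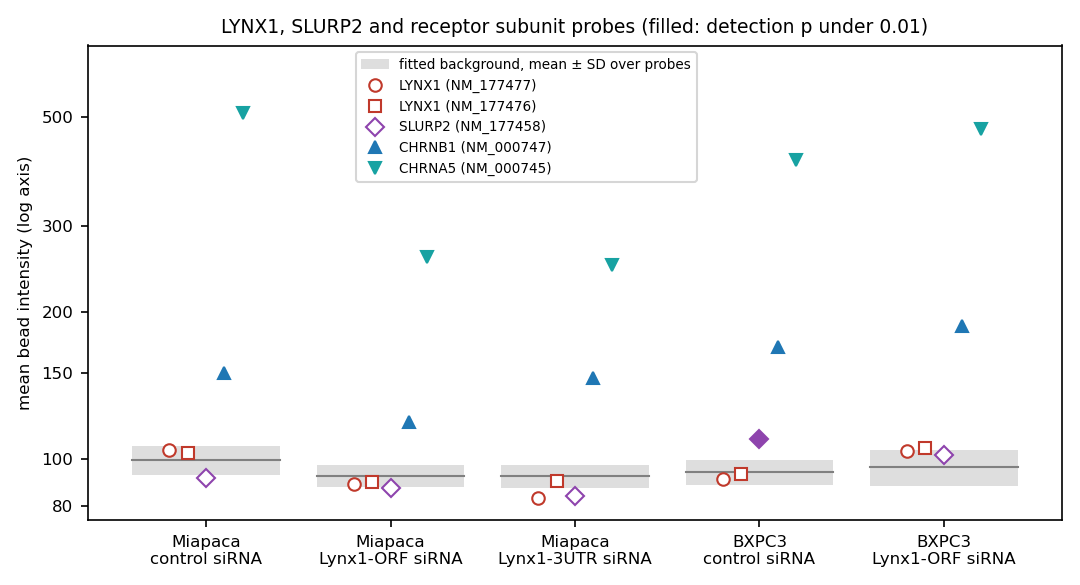
Mean bead intensity (y axis, log scale) of the LYNX1, SLURP2, CHRNB1 and CHRNA5 probes on the 5 arrays (x axis). Filled symbols mark a detection p under 0.01, and grey bands show the fitted background mean ± SD over probes; the LYNX1 symbols are open on all 5 arrays.

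In Miapaca cells the ORF siRNA array had lower DNA replication and mitosis genes and higher histone, epithelial and immediate early genes than the control array. The lowest gene was MLLT11, a fusion partner of KMT2A in leukaemia, with a log2 difference of −3.46. It was followed by SLC25A15, the mitochondrial ornithine transporter (9.71-fold lower), FAM199X (7.60-fold) and DNAJC10, a disulfide reductase of the endoplasmic reticulum (7.29-fold). The SLC25A15 value rests on 1 probe, since another gave a log2 difference of −0.10. TMEM30A, a flippase subunit, was at least 6.70-fold lower and C1GALT1C1, the chaperone of O-glycan core synthesis, 5.65-fold lower. Another C1GALT1C1 probe gave a smaller log2 difference of −0.79. The highest gene was H2BC5, an H2B histone, at 10.4-fold higher, while another of its probes gave 1.65 on the log2 scale. It was followed by ZNF467 (8.46-fold), PHLDA2 (7.51-fold) and SLC33A2 (7.45-fold). RN7SK, the 7SK RNA that holds the elongation factor P-TEFb, was 6.49-fold higher, and the small nucleolar RNAs SNORA80E and SNORA28 were 6.66-fold and 6.51-fold higher. Of 10899 genes compared, 553 were at least 2-fold higher and 600 at least 2-fold lower. Median scaling in place of quantile normalization moved the median of all genes to 0.15 and the counts to 1015 higher and 486 lower.

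Cell cycle lists stood far below matched random lists with the ORF siRNA. Of 34 measured G1/S and DNA replication genes, 31 lay below the control and 6 by at least 2-fold, with a list median of −0.62 that was lower than all 10000 random lists. TYMS, thymidylate synthase, was 5.25-fold lower, CDK2 4.75-fold, MCM10, a replication initiation factor, 4.14-fold, and CDK6 3.16-fold. Another MCM10 probe gave −1.22 on the log2 scale. Of the 2 arrays, another CDK2 probe was detected on the control array only. Of 35 G2/M genes, 31 lay below the control and 13 by at least 2-fold, with a list median of −0.81. They included the kinetochore gene NUF2 (3.67-fold lower), the spindle motor KIF11 (3.20-fold) and ANLN, which acts in cytokinesis (2.65-fold); another NUF2 probe gave −0.60 on the log2 scale. Of 22 p53 target and arrest genes, 15 lay above the control, and the list median of 0.30 was inside the middle 95% of random lists. CDKN1A, the CDK inhibitor p21, was 3.72-fold higher and SFN 3.37-fold higher, while SESN1 stood at −1.32 on the log2 scale. These cell cycle changes came with a control array whose mean intensity was 1.30 times that of the ORF array.

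Histone genes were higher with the ORF siRNA in 15 of 16 members, with 7 past 2-fold and a list median of 0.87. Labelling primed on poly(A) tails, so histone values, here and in the other comparisons, may not follow total histone RNA. H2BC21 was 5.01-fold, H2BC12 4.05-fold and H4C8 3.55-fold higher. Of 31 epithelial genes on the array, 15 were measured, and the rest were detected on neither of these arrays. All 15 were higher, with a list median of 0.97 (0.52 to 1.24 over 9 alternative settings) and 7 past 2-fold. They included MUC1, a membrane mucin (5.26-fold), the keratins KRT19 (3.33-fold) and KRT15 (2.74-fold), and CLDN3, a tight junction claudin (at least 2.57-fold). CLDN3 entered through its detection on the siRNA array alone. The immediate early and ERK target list had a median of 0.48 (0.27 to 0.54 over the settings), with FOSB at least 3.97-fold, IER3 3.52-fold and JUN 2.53-fold higher and FOSL1 2.56-fold lower. The lysosome and autophagy list had a median of 0.40, with the autophagy receptor SQSTM1 2.58-fold higher. The cholesterol and lipid synthesis list had a median of −0.37, with CYP51A1 2.25-fold and SQLE 2.15-fold lower. The ATF4 and unfolded protein response list had a median of 0.30 at the 97.51 percentile, and 3 of 9 alternative settings put it inside the random range. PPP1R15A was 3.35-fold and DDIT3 2.58-fold higher, and PSAT1 was 3.42-fold lower. The apoptosis and BCL2 family list had a median of −0.32 at the 2.195 percentile, which 7 of 9 settings put inside the range, with medians of −0.33 to −0.14; CYCS, cytochrome c, was 3.19-fold lower.

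The medians of the remaining lists with the ORF siRNA in Miapaca lay inside the range of random lists. They were −0.16 for interferon response, 0.08 for NF-kB, 0.05 for hypoxia and glycolysis, 0.28 for mesenchymal genes, 0.11 for ribosomal proteins, 0.04 for the respiratory chain and 0.02 for heat shock. They were 0.03 for NRF2 targets, −0.20 for metallothioneins, −0.25 for RNA interference machinery, 0.64 for the 4 measured fibroblast, endothelial and blood cell markers and −0.08 for reference genes. Pancreatic acinar and endocrine markers had 2 measured members in each comparison, too few for a percentile. VEGFA was 2.66-fold higher by its brightest probe, and its other probes were detected on neither of these 2 arrays.

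The 3UTR siRNA in Miapaca also went with lower cell cycle genes, and with lower metallothioneins and higher ATF4 and unfolded protein response genes. The lowest gene was HDGF, a growth factor found in the nucleus, at 16.3-fold lower. It was followed by TK1, thymidine kinase (10.6-fold lower), EML1 (8.03-fold), COPZ1, a COPI coat subunit (6.84-fold), and RNF20, a ubiquitin ligase for histone H2B (5.68-fold). With the ORF siRNA the same genes stood at −0.17, −0.70, −0.81, 0.39 and −0.34 on the log2 scale. Another EML1 probe, detected on 2 of the 5 arrays, gave −0.36 with the 3UTR siRNA. The highest genes were ZNF467 (7.45-fold), the galanin receptor GALR2 (4.75-fold), LRSAM1 (4.53-fold), CLK3 (3.98-fold) and RAB17 (3.87-fold). Of 10865 genes compared, 459 were at least 2-fold higher and 504 at least 2-fold lower. Median scaling moved the median of all genes to 0.15 and the counts to 966 higher and 369 lower.

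Of 35 G1/S genes, 28 lay below the control with the 3UTR siRNA, with a list median of −0.57 and 4 past 2-fold. MCM3 was 2.24-fold and E2F2 2.44-fold lower, and PCNA was 2.75-fold lower by 1 probe and −0.16 on the log2 scale by another. CCND3, cyclin D3, was 3.06-fold higher. Of 35 G2/M genes, 32 lay below the control, with a list median of −0.62 and 7 past 2-fold, among them CCNB1, cyclin B1 (2.91-fold lower), ANLN (2.64-fold) and NDC80 (2.32-fold). NUF2 was 3.10-fold lower by its brightest probe, while another gave 0.50 on the log2 scale. Of 25 ATF4 and unfolded protein response genes, 21 lay above the control and 8 by at least 2-fold, with a list median of 0.64. DNAJB9, an endoplasmic reticulum chaperone, was 2.90-fold higher, TRIB3, a pseudokinase induced by ATF4, 2.81-fold and SESN2 at least 2.57-fold, while EDEM1 was 3.12-fold lower. All 6 measured members of the metallothionein list lay below the control, with a list median of −1.10 (−1.10 to −0.66 over 9 settings). MT1M was 5.36-fold, MT1G 2.99-fold and MT2A 2.30-fold lower. The lysosome and autophagy list had a median of 0.40, which 1 of 9 settings, the mean over detected probes, put inside the random range at 0.24, with GABARAPL1 2.19-fold higher. Mean intensity on the control array was 1.35 times that on the 3UTR array.

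Other lists with the 3UTR siRNA stayed inside the range of random lists. Their medians were 0.18 for p53 targets, 0.20 for apoptosis, 0.22 for interferon response, −0.10 for NF-kB, 0.14 for immediate early genes, 0.06 for hypoxia and glycolysis, 0.18 for cholesterol synthesis and 0.13 for epithelial genes. They were 0.13 for mesenchymal genes, 0.10 for ribosomal proteins, 0.05 for the respiratory chain, 0.07 for heat shock, 0.08 for NRF2 targets, 0.25 for histones, 0.05 for RNA interference machinery, 0.44 for fibroblast, endothelial and blood cell markers and −0.10 for reference genes. In these lists CDKN1A was 2.37-fold higher, the interferon-induced IFIT3 and ISG15 were 2.71-fold and 2.28-fold higher, and H2AC25 was 3.27-fold higher.

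The 2 siRNAs in Miapaca correlated at a level that a shared control array can give by itself. Across 10447 genes the log2 differences correlated at r = 0.51, beside 0.50 in simulated unchanged arrays with the same control. Unchanged arrays of equal spread with a shared control give an r near 0.50 at any spread, so this benchmark was fixed in advance. The covariance of the log2 differences was 0.197 beside a simulated 0.190 (SD 0.00494 over 100 simulations), an excess of 0.00709. Past 2-fold, 117 genes were higher and 123 lower with both siRNAs, 240 in all, and 7 went opposite ways. The simulation, which set no gene at a bound, gave 320 in all, and independent lists would give 19.6 and 28.9. The simulated spread was taken from the ORF and 3UTR arrays themselves. It therefore holds any real difference between the siRNAs and may set the simulated covariance and overlap too high. The simulation therefore cannot tell whether the siRNAs share a response. The single control array could not be split, so part of the overlap may come from it. Genes are not independent replicates in these correlations. MLLT11 and HDGF differed most plainly between the siRNAs, at −3.46 and 0.88 for MLLT11 and −0.17 and −4.03 for HDGF with ORF and 3UTR siRNA. ZNF467 was among the highest genes with both, at 3.08 and 2.90.

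In BXPC3 cells the ORF siRNA array differed less from its control, with lower cell cycle and interferon genes and higher histone genes. The lowest gene was AKR1C2, an aldo-keto reductase of steroid metabolism, at 3.03-fold lower. TNFSF10, the death ligand TRAIL, was at least 2.72-fold lower, SLC8A3 at least 2.64-fold and NUAK2, a kinase of the AMPK family, 2.46-fold lower. The highest was SPRR2D, a cornified envelope protein, at least 4.93-fold higher, followed by DOK1 (at least 4.33-fold), ZNF763 (3.22-fold) and AGR2, a disulfide isomerase of secretory cells (3.14-fold). H2BC5 was 3.12-fold higher and IL1RL1, the interleukin-33 receptor, 2.93-fold higher. Of 11252 genes compared, 71 were at least 2-fold higher and 52 at least 2-fold lower. The authors' series matrix values gave 6 higher and 1 lower.

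Of 34 G1/S genes, 32 lay below the BXPC3 control, with a list median of −0.38, and of 35 G2/M genes 30 did, with a median of −0.25. Both medians were lower than all 10000 random lists, and no member of either list passed 2-fold. The interferon response list had a median of −0.35 (−0.35 to −0.23 over 9 settings), with 25 of 32 members below the control. OAS1 was 2.12-fold and IFI44L 2.06-fold lower, and another IFI44L probe gave −0.33 on the log2 scale. The NF-kB list had a median of −0.17, although MMP1 was 2.14-fold higher. All 13 measured histone genes lay above the control, with a list median of 0.61 (0.38 to 0.61 over the settings) and H2BC21 2.09-fold higher. The ATF4 list had a median of 0.21 with 21 of 27 members above the control, and TRIB3 was 2.28-fold higher. The heat shock list had a median of −0.11 at the 2.11 percentile, which 4 of 9 alternative settings put inside the random range, with medians of −0.12 to −0.07, and HSPB8 went the other way at 2.42-fold higher. The mean intensity of the BXPC3 control array was 1.02 times that of the ORF array.

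The medians of the other BXPC3 lists lay inside the random range. They were 0.04 for p53 targets, −0.08 for apoptosis, −0.01 for immediate early genes, −0.09 for hypoxia and glycolysis, −0.09 for cholesterol synthesis, 0.01 for epithelial genes, 0.13 for mesenchymal genes and 0.02 for ribosomal proteins. They were 0.01 for the respiratory chain, −0.10 for NRF2 targets, 0.02 for metallothioneins, 0.07 for lysosome and autophagy, 0.02 for RNA interference machinery, 0.07 for fibroblast, endothelial and blood cell markers and −0.06 for reference genes. KRT5, a basal keratin, was 2.22-fold lower.

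**Figure D2:**
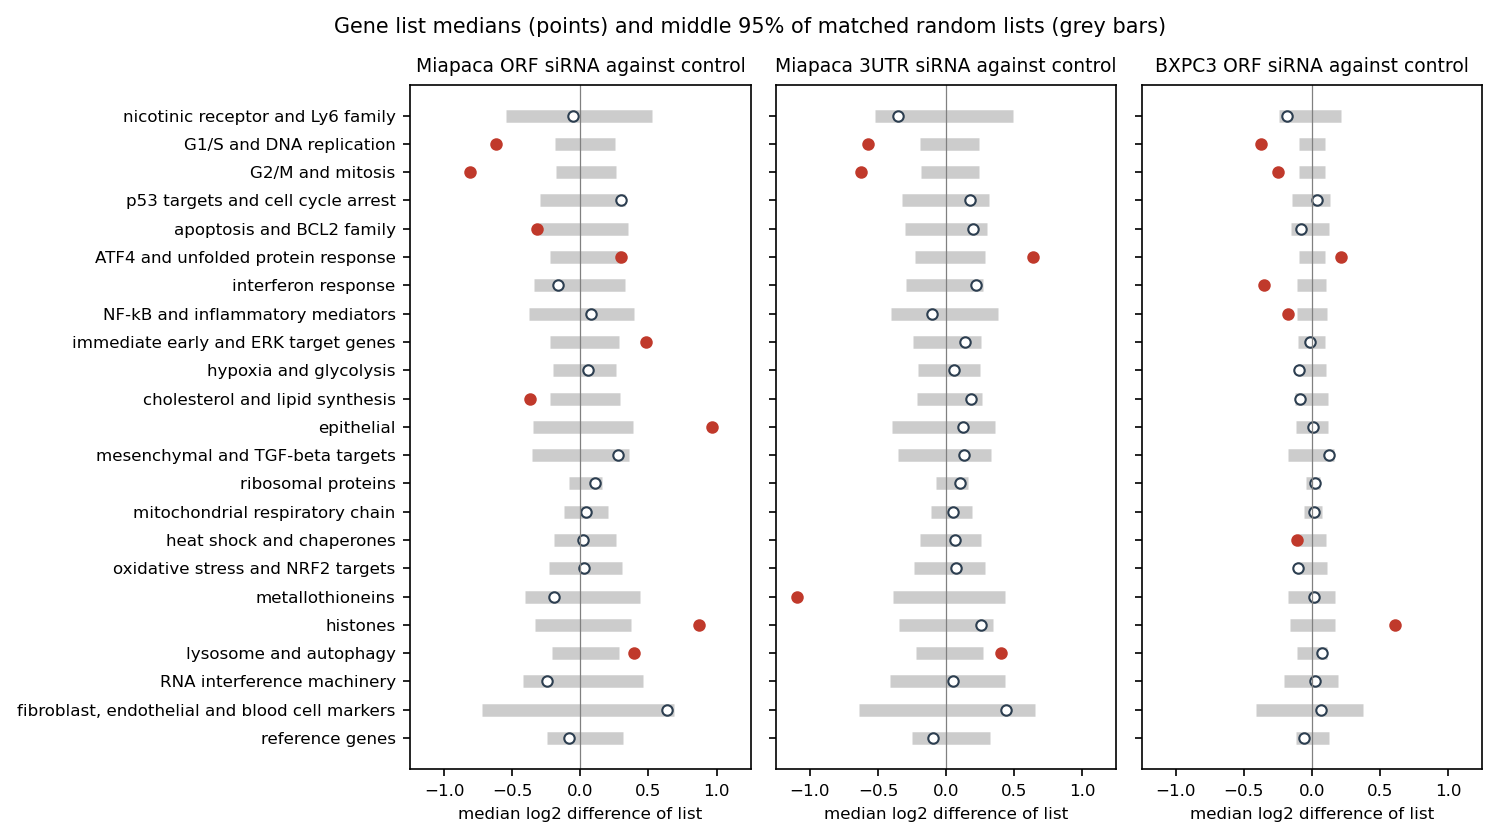
Median log2 difference from control (x axis) of each gene list (y axis) in the 3 comparisons, as points, beside grey bars for the middle 95% of 10000 matched random lists. Filled red points lie outside that range; the G1/S and G2/M medians lie to the left of it in all 3, from −0.81 to −0.25.

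The ORF siRNA was used in both lines, which share no array. Across 9567 genes its log2 differences in Miapaca and BXPC3 correlated at r = 0.26 (Spearman's rho 0.24). The 3UTR siRNA in Miapaca and the ORF siRNA in BXPC3 correlated at r = 0.08 across 9559 genes. The difference between the ORF and 3UTR arrays in Miapaca, computed after the results had been seen, correlated with the ORF siRNA in BXPC3 at r = 0.20 across 9139 genes. These were the 3 correlations computed across lines. With the ORF siRNA, 8 genes were at least 2-fold higher in both lines and 5 at least 2-fold lower, where independent lists would give 1.66 and 1.87, and 0 genes passed 2-fold in opposite directions. The lists that stood apart the same way in all 3 comparisons were G1/S, G2/M and ATF4, the last at the edge of the random range with the ORF siRNA in Miapaca. The histone list stood apart with the ORF siRNA in both lines, at 0.87 and 0.61, and not with the 3UTR siRNA, at 0.25; the difference between siRNAs was not tested. The epithelial list stood apart with the ORF siRNA in Miapaca at 0.97 and lay at 0.01 in BXPC3, a difference that was also not tested.

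At least 2-fold the same way in all 3 comparisons were 4 of 9399 genes, where 0.748 would be met if BXPC3 were independent of Miapaca; the 2 Miapaca comparisons share their control array. FAM111B, a serine protease, was at least 2.40-fold lower with the ORF siRNA and at least 2.37-fold lower with the 3UTR siRNA in Miapaca, and 2.36-fold lower in BXPC3. H2BC5 was 10.4-fold, 2.74-fold and 3.12-fold higher, although another H2BC5 probe gave 1.65, 0.14 and 1.11 on the log2 scale. TRIB3 was 2.24-fold, 2.81-fold and 2.28-fold higher. PTPRH, a receptor tyrosine phosphatase, was 2.14-fold, 2.02-fold and at least 2.67-fold higher.

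**Figure D3:**
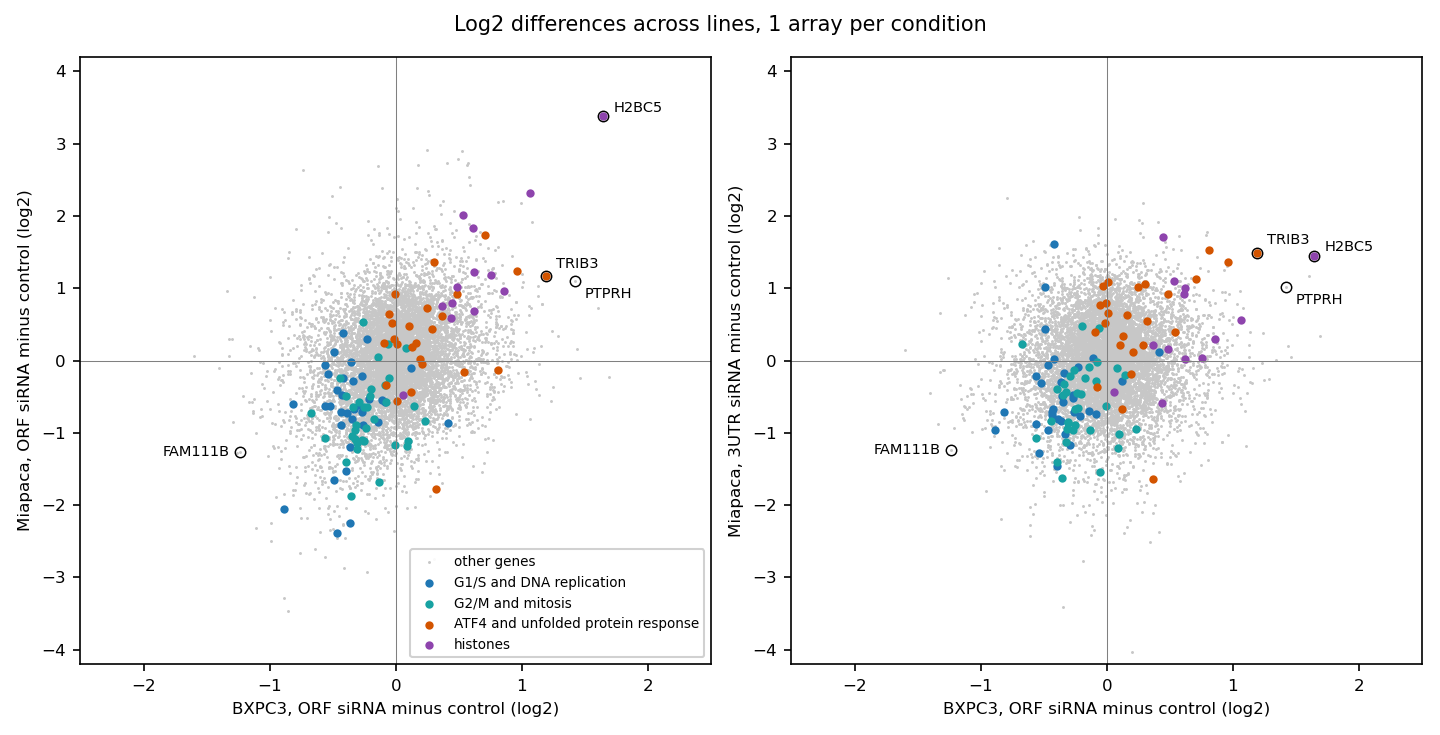
Log2 difference from control in Miapaca (y axis; ORF siRNA left, 3UTR siRNA right) against that of the ORF siRNA in BXPC3 (x axis), each point 1 gene measured in both. Colours mark 4 gene lists and circles the 4 genes past 2-fold in all 3 comparisons; the correlation is 0.26 on the left and 0.08 on the right.

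Over all 5 arrays, limma with a line term called 0 of 12842 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.894. At an unadjusted p under 0.05 there were 547 genes, fewer than uniform p-values would give. The genes with the smallest p were FAM111B (log2 difference −1.26 ± 0.238, SE), TRIB3 (1.27 ± 0.252), PTPRH (1.21 ± 0.247), SESN2 (1.16 ± 0.247) and ZNF670 (−1.17 ± 0.259). Camera with the preset correlation put G2/M (adjusted p = 4.06e-11) and G1/S (2.57e-10) lower, with list medians of −0.50 and −0.50. It put histones (4.34e-07), ATF4 (1.30e-05), lysosome and autophagy (0.00869) and epithelial genes (0.0436) higher, with medians of 0.61, 0.30, 0.17 and 0.18. At the same correlation, median scaling ended the call for lysosome and autophagy (adjusted p = 0.177) and the mean over detected probes that for epithelial genes (0.0750). No list kept its call with an estimated correlation, where the smallest adjusted p was 0.754. That setting also tests on the 2 residual degrees of freedom, so the lost calls need not reflect correlation between genes. For lysosome and autophagy the estimated correlation was 0.019, near the preset 0.01, yet the camera p went from 0.00181 to 0.104. Adjusted over the list alone, 2 ATF4 members and 1 p53 member passed 0.05 in limma, and 0 did over all genes.

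Without the 3UTR array, the same limma fit on the ORF and control arrays of both lines, with 1 residual degree of freedom, called 95 genes, 39 higher and 56 lower. H2BC5 had the smallest adjusted p (1.22e-06, log2 difference 2.51), followed by MLLT11 (0.000281, −2.16) and SLC25A15 (0.000286, −2.08). H2BC5, MLLT11 and SLC25A15 were higher or lower the same way in both lines, but not all of the 95 genes rested on both. KCNK6 had log2 differences of 2.71 in Miapaca and 0.18 in BXPC3, and FAM199X had −2.93 and −0.23. ZNF467 was detected on neither BXPC3 array, and SPRR2D on no Miapaca array. The error estimate of this fit was mostly borrowed across genes, with a prior of 60.6 degrees of freedom beside 5.33 in the fit over 5 arrays. Camera at the preset correlation kept its calls there for G1/S, G2/M, histones, ATF4 and epithelial genes, lost lysosome and autophagy (adjusted p = 0.0597), and put interferon response lower (0.0419) and immediate early genes higher (0.0321). With an estimated correlation, which again tests on the residual degrees of freedom, no list kept a call, and the smallest adjusted p was 0.692. The count depended on the processing, with 77 genes under median scaling, 65 of them shared, 1 each under no background correction, an offset of 50 and cyclic loess, and 0 with quantile normalization within each line or with the authors' series matrix values.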

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

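With the ORF siRNA, 3 named genes stood out because they moved in opposite directions in the 2 lines by at least 1.5-fold each way. TELO2 was set aside, because in each line the brighter of its 2 arrays was not above the detection limit. With 1 array per condition the difference between the lines was not tested. COL1A2, a collagen chain, had a log2 difference from control of 0.88 in Miapaca and of −1.12 or lower in BXPC3, where the siRNA array was not above the detection limit and another COL1A2 probe was detected on neither array. The log2 differences of GALR2 in Miapaca and BXPC3 were 1.83 and −0.79 or lower, the latter again with the siRNA array below the detection limit. The interferon-regulated transcription factor IRF1 had 0.68 and −0.60.

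Probes without a single gene name were outside every comparison and also differed from the control arrays. At least 2-fold above the control were 192 such probes with the ORF siRNA in Miapaca, 204 with the 3UTR siRNA and 53 in BXPC3, of 4461, 4520 and 4860 detected. At least 2-fold below it were 175, 183 and 45. They remain without gene names here.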

How the results depend on the processing

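Replicates could not be paired within a line because each group holds 1 array; the limma fit without the 3UTR array takes each line as a pair. Counts past 2-fold depended on how background was treated. Without background correction they were 146 higher and 196 lower (Miapaca ORF), 92 and 140 (Miapaca 3UTR), 5 and 1 (BXPC3), and 48 the same way with both siRNAs in Miapaca. With an offset of 50 they were 244 and 305, 184 and 247, 11 and 3, and 96. The authors' series matrix values gave 164 and 197, 104 and 147, 6 and 1, and 55. Adding a larger constant to both arrays lowers every fold by construction. The matrix values had column medians of 100.0 to 102, near the uncorrected bead medians of 96.7 to 106, and their counts lay close to those without background correction. Their normalization method is not given, so the cause was not tested further. Median scaling gave 1015 higher genes for Miapaca ORF and 966 for Miapaca 3UTR. It moved the computed LYNX1 log2 difference to 0.45 and 0.54, although LYNX1 was below background on all 5 arrays and these numbers measure no level. This scaling moves all probes of an array by the same amount, set by the median of probes detected on all 5 arrays. Before scaling that median was 8.43 on the Miapaca control, 7.73 with the ORF siRNA and 7.66 with the 3UTR siRNA. The 2 siRNA arrays were thereby raised against the control, also at background. Genes detected on both arrays only numbered 39 higher and 27 lower in BXPC3, since fewer genes entered. A 1.5-fold threshold gave 1827 and 1768, 1687 and 1652, 579 and 548, and 1410. Without a detection filter the correlation of the ORF siRNA across lines was 0.164, the cause of which was not tested. Limma without the 3UTR array called 95 genes in place of 0, and 20 simulations of unchanged genes for that fit gave at most 0 false calls. The simulations took independent genes with spreads estimated on 1 degree of freedom. Such spreads scatter more than the fit's prior of 60.6 degrees of freedom implies, so the simulations cannot show how many of the 95 calls are false.

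Genes at an unadjusted p under 0.05 in limma went from 547 of 12842 to 70 without the line term, where differences between the lines count as error. They numbered 896 of 20043 without a filter, where more genes entered. They numbered 903 under median scaling and 1257 without the 3UTR array, where the cause was not tested. The 95 calls of limma without the 3UTR array fell to 1 without background correction and to 0 with the series matrix values, among the settings given in the Results. Other counts past 2-fold or past an adjusted p of 0.05 stayed within 1.5 times of the reported ones, and no value in the text with a call changed sign. Of the alternatives for named genes, 865 stayed within 1.5-fold of the main value, a fixed limit. The other 209 moved further, 85 of 179 without background correction, 84 of 179 with the series matrix values and 40 of 179 with an offset of 50. Of those for gene list medians, 585 stayed on their side of the random range, 15 moved inside it and 21 moved outside it; the camera calls stayed in 183, weakened in 8 and strengthened in 1. The G1/S and G2/M medians stood apart in 9 of 9 settings in each comparison, between −0.84 and −0.21. Low signal over background also limits the values. Where a gene with 2 detected probes could be compared, the probes differed by a median of 0.34 (Miapaca ORF), 0.37 (Miapaca 3UTR) and 0.20 (BXPC3) on the log2 scale. Where the brightest probe passed 2-fold, another probe had the same sign for 193 of 221, 158 of 189 and 15 of 18 genes, and it also passed 2-fold for 87, 61 and 4 of them.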

Other observations

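Apart from the gene lists and their percentiles in the siRNA comparisons, which were fixed before the data were examined, all tests and comparisons in this part were chosen only after the results had been seen. The 2 control arrays separated the lines by epithelial and interferon genes. EPCAM was at least 211-fold, the keratin KRT7 at least 125-fold and the E-cadherin gene CDH1 at least 83.9-fold brighter in BXPC3, and VIM, vimentin, was 219-fold brighter in Miapaca. Of 26 measured epithelial genes, 21 were at least 2-fold higher in BXPC3, with a median log2 difference of 3.10 between the lines. The collagen gene COL5A2 was at least 112-fold higher in Miapaca, yet the mesenchymal list had a median of 0.99 in favour of BXPC3, which had more TGFBI (13.7-fold) and SNAI2 (at least 39.1-fold). Of 34 interferon genes, 23 were at least 2-fold higher in BXPC3 and 0 in Miapaca, among them IFI27 (at least 454-fold), IFI44 (108-fold) and ISG15 (16.9-fold). OAS1 and IFI44L, which were lower with the ORF siRNA in BXPC3, were at least 6.08-fold and 52.9-fold brighter on its control array than on that of Miapaca. Of 11825 genes compared, 1741 were at least 2-fold higher in BXPC3 and 1695 in Miapaca. The lines also differed in medium, siRNA dose and transfection reagent.

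Small nuclear, Cajal body and nucleolar RNAs, taken from the annotation as a class, stood higher with the ORF siRNA in Miapaca. Under labelling that primes on poly(A) tails, it was not tested whether values of this class, or of RN7SK, follow the total amounts. Of 171 measured, 29 were at least 2-fold higher and 2 at least 2-fold lower, and the median of 0.21 lay at the 99.97 percentile of matched random sets. With the 3UTR siRNA the median was −0.03, with 12 higher and 4 lower, and in BXPC3 it was −0.02, with 0 of 149 past 2-fold. Long non-coding RNAs had medians of 0.07, 0.10 and 0.07 in the 3 comparisons, the last 2 above the middle 95% of random sets.

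The 2 siRNAs against LYNX1 gave different profiles in Miapaca, with 495 genes at least 2-fold lower and 535 at least 2-fold higher with the ORF siRNA than with the 3UTR siRNA. Noise that strikes genes independently on these 2 Miapaca arrays is argued against as the whole cause by BXPC3, which shares no array with them. There, the 446 measured genes of the lower set had a median of −0.24 with the ORF siRNA (matched random sets −0.04 to 0.03; 336 of 446 lower), and the 458 of the higher set had a median of 0.066 (random −0.03 to 0.03; 265 of 458 higher). The random sets were drawn gene by gene, so genes that vary together between single cultures could also shift these medians. Leaving out the members of the cell cycle lists took 5 of the 446 genes away and left a median of −0.24, which cannot tell whether an effect tied to the ORF siRNA goes beyond cell cycle genes. A deeper loss of LYNX1 with the ORF siRNA and pairing of that siRNA with other transcripts cannot be told apart, since LYNX1 was detected on 0 of 5 arrays and no transcript sequences were searched.

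Genes at least 2-fold lower or higher with both siRNAs in Miapaca share a single control array. That array as the whole cause is argued against by BXPC3, where 108 measured genes of the lower set had a median of −0.17 (random sets −0.08 to 0.06) and 102 of the higher set a median of 0.15 (random −0.07 to 0.06). Because these genes were picked partly on the ORF array, the medians may also reflect an effect of the ORF siRNA alone. They may also reflect genes that vary together between single cultures, which the random sets do not hold. How much of the overlap the control array supplied stays open.

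The G1/S, G2/M and ATF4 lists stood apart in the same direction in all 3 comparisons, although the ATF4 list with the ORF siRNA in Miapaca lay at the 97.51 percentile and 3 of 9 settings put it inside the random range. A brighter control array is argued against as the cause in BXPC3, whose control array had 1.02 times the mean intensity of its ORF array. The Miapaca control array had 1.30 and 1.35 times the mean intensity of the ORF and 3UTR arrays. How much of the larger Miapaca list shifts came from that was not tested, and BXPC3 cannot show it. A response to loss of LYNX1 may account for the pattern, and so may a response to these siRNAs that does not run through LYNX1. These 2 cannot be told apart, because LYNX1 was detected on 0 of 5 arrays. With 1 culture per condition, differences between the cultures other than the siRNA cannot be told apart from either. Arrays of untransfected cells or of another non-targeting siRNA were not analysed here.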
